A study of Danio rerio with 30 samples.

How the data were processed

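Gene expression was measured in 30 zebrafish samples on Affymetrix arrays, 3 arrays in each of 10 groups: control, chlorpyrifos (CPF, an organophosphate insecticide) at 0.1, 0.25 and 0.6, copper (Cu) at 0.1, 0.25 and 0.6, and CPF at 0.1, 0.25 and 0.6 together with Cu at 0.25. The concentration unit is not given in the sources used here. The labels differ on the tissue: the source field names olfactory rosettes, and the tissue field adds the olfactory bulbs and telencephalons. Replicates were numbered in accession order and never paired. The labels speak of 30 fish in groups of 3, and nothing in them says whether the replicates were independent, so p-values measure the spread between these arrays only.

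The deposited table held log2 expression values made with GCRMA, per the submitters' processing notes, with no version given in the sources used here. That the values are log2 was inferred from their range, 1.02 to 15.73. The table had 15617 probe sets, of which 115 were control probe sets and were left out of all tests. Of the other 15502, the platform annotation gave 1 gene symbol to 10795 and several to 135. It named no gene for 4572 in the annotation used here. Symbols were updated through the gene identifier where the reference gene table allowed, which changed 1. No gene was named from a probe set with several symbols. Detection calls were not used here.

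Probe sets above 4 on the log2 scale in at least 3 arrays were kept, which left 10531 probe sets, 7619 of them with 1 symbol, for 6448 genes. No further normalization was applied. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 30 arrays, with a mean per group and a fixed term for the batch read from the sample titles. The titles carry dates, read here as batches, and nothing in the labels says whether they are of exposure, hybridization or scanning. There were 3 such title batches of 12, 13 and 5 arrays, with 18 residual degrees of freedom. They were uneven over groups. Title batch 3 held control replicate 1 and 1 array each of Cu 0.25, Cu 0.6 and the mixtures with CPF 0.25 and 0.6. Cu 0.6 had no array in title batch 1. A fit without title batch 3 therefore also lost arrays of those groups, and cannot tell a batch difference from fewer arrays. Adjusted p-values are Benjamini-Hochberg values over the 10531 probe sets, with a threshold of 0.05. Comparisons were each group against control, each mixture against each of its agents alone, Cu 0.25 averaged over the 4 CPF levels, CPF averaged over the 2 copper levels (an F-test), the CPF by Cu interaction (an F-test), any difference among groups, and a trend over the rank of the concentration for each agent. The comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Copper against CPF at the same number, all CPF levels against none, and a fit without 4 arrays rich in liver or pancreas transcripts were added after seeing the data. Those 4 were CPF 0.25 replicate 1 and 3, Cu 0.25 replicate 3 and CPF 0.6 replicate 2, which left CPF 0.25 with 1 array.

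Named genes were the 8 highest and 8 lowest fold changes among probe sets past the threshold with 1 symbol, using the probe set with the highest mean for each gene. For a single group, all 3 of its arrays had to lie on the same side of all 3 control arrays once the batch terms were removed. Up to 4 members of each fixed list past the threshold were added, as were the 10 smallest p-values of an F-test, and the 5 smallest p-values where fewer than 5 probe sets passed. The genes ache, mt2, hmox1a, ompb, gnal, the hsp70 family and the haemoglobins were always named if measured. mt2, hmox1a and gnal were not among the genes kept. The text gives values for part of the genes this rule names, and that part was chosen after their values and their stability were seen. Genes named outside this rule are said to be so.

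There were 32 lists of genes fixed in advance, for stress responses, signalling, metabolism and cell types, and 27 of them had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01. Each test was repeated with an estimated correlation. Lists added later are named as chosen after seeing the data. Correlations of fold changes across probe sets were set beside 100 simulations of unchanged groups with the same design.

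The alternatives were no batch term, batch as a random block, no arrays of title batch 3, no filter, a filter at 6, quantile normalization, median centring, a trended and robust prior, array weights, a fit of the compared groups alone, fits within a title batch, the mean of all probe sets of a gene in the list tests, and leaving out each array in turn. The fits were tested on simulated data in which known changes were added to the real design. In the comparison of Cu 0.6 with control, run on 10531 probe sets, 34.8% of changes of 0.5 on the log2 scale were recovered, 89.6% of changes of 1 and 98.5% of changes of 2. For CPF 0.6 against control the shares were 34.8%, 94.0% and 98.5%, and for the interaction 7.58%, 56.7% and 94.0%. For Cu 0.25 averaged over CPF levels they were 90.9%, 98.5% and 100%. Each simulation changed 66, 67 and 67 probe sets by these 3 sizes at once, with independent noise. Many true changes ease the Benjamini-Hochberg threshold. The shares are therefore too high for comparisons with few calls, such as CPF 0.6 against control and the interaction. The number of arrays limits the precision. Figures were drawn with matplotlib.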

Results

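The arrays measured transcripts of zebrafish olfactory tissue after exposure to CPF, to copper, or to both, with 3 arrays for each of 10 groups. Array medians lay between 5.53 and 5.63 on the log2 scale, and between 9782 and 10416 probe sets per array exceeded 4. Correlations between arrays ran from 0.962 to 0.993, with a median of 0.984 within groups and 0.982 between groups, and no 2 arrays were identical. Control replicate 1 lay farthest out on the first principal component, which held 13.5% of the variance.

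The averaged effect of copper at 0.25, from 12 arrays with copper and 12 without, asked what copper did on average over the 4 CPF levels. It does not show an effect at each of them. Olfactory genes fell: ompb, the olfactory marker protein, by −1.26 ± 0.19 (SE) log2, s100z, a calcium-binding protein, by −1.51 ± 0.20, and gng13b, a G protein gamma subunit, by −0.89 ± 0.08. The calcium-binding proteins calb2a (calretinin, −1.38 ± 0.15), pvalb5 (−1.36 ± 0.14) and pvalb8 (−1.47 ± 0.25) fell too; calb2a is also in the fixed list of bulb and telencephalon markers and pvalb8 in that of epithelium and skin. So did the sulfotransferases sult2st1 (−1.82 ± 0.19) and sult2st2 (−1.58 ± 0.17). Of 6 measured olfactory receptor genes 5 fell, among them or42c4 by −1.30 ± 0.17, and all 6 passed when adjusted over the list alone. Without the arrays of title batch 3 the number was 3, with quantile normalization 2, and with no filter 12 of 23. With the filter at 6 only 1 receptor gene was measured, and it did not pass. The calls of or42c1, or42d1 and or42e1 ended with quantile normalization. That of or42c1 also ended without 4 arrays rich in liver or pancreas transcripts. Each gene named so far in this paragraph except or42c1 (10 of 12) lay below the median of the arrays without copper in 12 of 12 arrays with copper, after removal of the batch terms. The ferritin gene fthl28 rose by 2.78 ± 0.63, the heat shock gene hsp70.3 by 1.79 ± 0.44 and its cochaperone dnajb1b by 0.92 ± 0.15, also in 12 of 12 arrays. The calls of fthl28 and hsp70.3 ended without the arrays of title batch 3 and without 4 arrays rich in liver or pancreas transcripts (adjusted p = 0.0950 and 0.132), and that of hsp70.3 ended without control replicate 1 (adjusted p = 0.0633).

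Among early response and cytokine feedback genes, klf2a fell by −1.21, dusp1 by −0.92, socs1a by −0.93 and socs3a by −0.90. Without the same 4 arrays socs1a was at −0.62 and socs3a at −0.77, and neither passed (adjusted p = 0.148 and 0.0738). The macrophage receptor marco rose by 0.98 and the complement gene c1qc by 0.91. Of 32 measured cell cycle and replication genes 8 rose, including mcm2 by 0.81, dut by 0.73 and rrm1 by 0.58, and 14 rose when adjusted over the list alone. ascl1a and sox3, transcription factors of neural precursors, rose by 0.85 and 0.37. The calls of rrm1 and sox3 ended with no batch term and with batch as a random block, and that of sox3 ended without the arrays of title batch 3. The interferon-induced gene isg15 rose by 0.94 ± 0.26 and tyms, thymidylate synthase, by 0.67 ± 0.17, but they passed in 7 and 18 of the 24 fits that left out an array, and neither passed without title batch 3 or without the 4 arrays, nor isg15 with no batch term, a random block or no filter. The acetylcholinesterase gene ache changed by 0.14 ± 0.15 (limma adjusted p = 0.658, higher in 5 of 12 arrays).

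In total 458 probe sets passed, 229 higher and 229 lower, for 341 genes, and 2036 had an unadjusted p under 0.05 against 526.55 expected. Without control replicate 1 the count was 299. It was 0 within title batch 1 and 38 within title batch 2, which hold fewer arrays, and the change of ompb was −1.21 and −1.32 within them. Without the arrays of title batch 3 the count was 229, and with array weights it was 782.

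With camera 11 of the 27 tested lists passed for averaged copper, and 1 of them, the olfactory receptors, did so with an estimated correlation (adjusted p = 0.0162). Of 28 immediate early genes 6 fell and 11 fell when adjusted over the list alone (adjusted p = 0.159 with an estimated correlation), and 4 fell without the arrays of title batch 3. Of 11 olfactory transduction genes 4 fell (adjusted p = 0.201 with an estimated correlation). Of 25 cell death and p53 target genes 3 fell (adjusted p = 0.201 with an estimated correlation). The cell cycle list rose (adjusted p = 0.478 with an estimated correlation), as did oxidative phosphorylation, with 3 of 84 members higher (adjusted p = 0.575 with an estimated correlation), or 0 without title batch 3 and 1 with quantile normalization. Heat shock genes (2 of 19 higher) and circadian clock genes (2 of 22 lower) had adjusted p = 0.478 with an estimated correlation. Inflammatory genes (1 of 33 higher, 4 lower) and epithelium markers (1 of 29 higher, 2 lower) had adjusted p = 0.575 with an estimated correlation, and no ribosomal protein gene of 74 passed (adjusted p = 0.81 with an estimated correlation).

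The other fixed lists did not pass for averaged copper. Of 14 metal response genes 0 passed over all probe sets, and 3 rose and 2 fell when adjusted over the list alone. Oxidative stress genes had 2 of 23 higher and 1 lower, xenobiotic metabolism 1 of 17 higher and 1 lower, and neurogenesis 2 of 26 higher. Calcium-binding proteins had 3 of 19 lower, with a median of 0.05 and a mean of −0.15. Synapse genes had 1 of 23 lower, markers of bulb and telencephalon neurons 2 of 11 lower, and microglia and macrophage markers 2 of 16 higher. No member passed among cholesterol synthesis (8), radial glia (10), oligodendrocyte (9), neutrophil (5), erythrocyte (8), connective tissue (7), ciliated cell (20) and retina (14) genes. The calcium-binding, synapse, cholesterol, bulb neuron, oligodendrocyte, erythrocyte and retina lists had positive medians and a negative test direction. Both measured markers of olfactory sensory neurons fell, and cholinergic genes (3 measured), skeletal muscle (2), pituitary (1) and lymphocyte markers (0) were too few to test, with 0 past the threshold. Within title batches 1 and 2 the median of cell cycle genes was 0.20 and 0.26, that of immediate early genes −0.11 and −0.30, and that of epithelium markers −0.24 and −0.02.

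**Figure D1:**
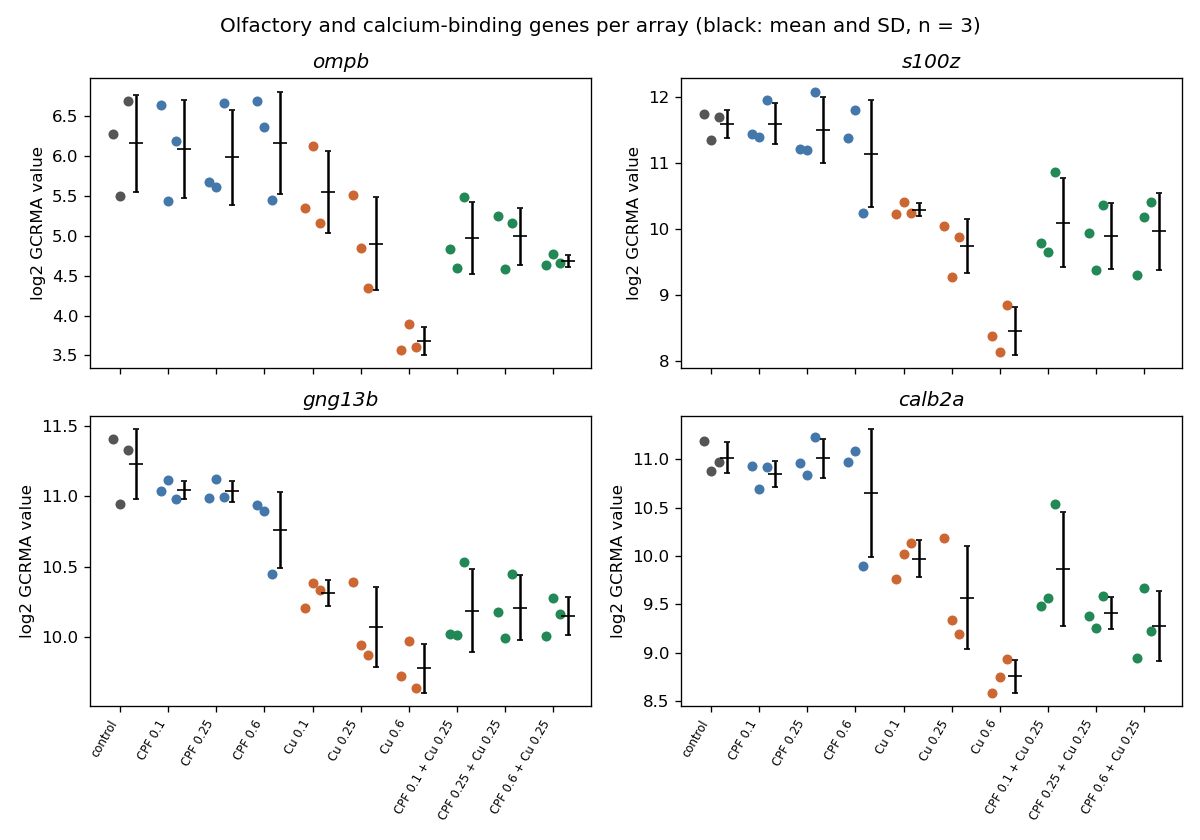
Log2 GCRMA values of ompb, s100z, gng13b and calb2a in each of the 30 arrays by group, with the mean and SD of the 3 arrays in black. The mean of ompb was 6.15 in the control arrays and 3.68 at Cu 0.6.

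Copper alone was compared with control at 3 concentrations. At Cu 0.6 s100z fell by −3.18 ± 0.39, pvalb8 by −3.44 ± 0.49, ompb by −2.48 ± 0.39 and calb2a by −2.30 ± 0.30, each in 3 of 3 arrays. socs1a fell by −3.19 ± 0.40, socs3a by −2.40 ± 0.34, the sodium pump subunit atp1a1a.3 by −2.84 ± 0.46 and the antioxidant enzyme nqo1 by −1.24 ± 0.27. The lysosomal proteases ctsba (cathepsin B) and lgmn (legumain) rose by 1.14 ± 0.15 and 0.96 ± 0.17, and the neuropeptide genes gnrh3 and npffl by 1.74 ± 0.41 and 1.85 ± 0.44. The neuropeptide gene nmbb rose 3.04-fold (adjusted p = 0.0252) and the zinc transporter slc30a7 by 0.50 ± 0.11 log2, and they passed in 2 and 0 of the 6 fits that left out an array. hsp70.3 was at 0.66 ± 0.87 (adjusted p = 0.775, 1 of 3 arrays above all controls). The calls of gnrh3, npffl and nqo1 ended without Cu 0.6 replicate 1 or 2 or control replicate 1 or 3, that of gnrh3 also without control replicate 2, and that of nqo1 also without Cu 0.6 replicate 3. These calls and those of lgmn, nmbb and slc30a7 ended without the arrays of title batch 3, those of lgmn, nmbb and slc30a7 also with the 2 groups fitted alone, and that of slc30a7 with quantile normalization. Those of s100z, pvalb8, ompb, calb2a, socs1a, socs3a, atp1a1a.3 and ctsba held in all 6 fits that left out an array.

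For Cu 0.6, 171 probe sets passed, 72 higher and 99 lower. The count was 103, 68 and 108 without Cu 0.6 replicate 1, 2 and 3 and 59 without control replicate 1. It was 36 without the arrays of title batch 3, 50 with the 2 groups fitted alone and 374 with array weights. Olfactory receptors and immediate early genes were lower as lists (adjusted p = 0.177 and 0.36 with an estimated correlation). Olfactory transduction genes were lower in the test although their median was 0.08 (adjusted p = 0.36 with an estimated correlation).

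At Cu 0.25, s100z fell by −1.86 ± 0.39, pvalb5 by −1.59 ± 0.27, gng13b by −1.16 ± 0.16 and sult2st1 by −1.91 ± 0.37, and the NF-kappaB inhibitor gene nfkbiab fell by −1.29 ± 0.25. ctsba rose by 0.95 ± 0.14, lgmn by 0.79 ± 0.17, ctsd (cathepsin D) by 0.51 ± 0.10 and sox3 by 0.78 ± 0.16. In all 37 probe sets passed, 8 higher and 29 lower. ctsba and gng13b passed in 5 of the 6 fits that left out an array, and the other genes named here in 1 to 3 of them. None passed without control replicate 1, 3 did without Cu 0.25 replicate 2 and 5 without control replicate 3. The calls of s100z, pvalb5, sult2st1, nfkbiab, lgmn and sox3 ended without 4 arrays rich in liver or pancreas transcripts, and those of ctsba, gng13b, ctsd, lgmn and sox3 with the 2 groups fitted alone. Those of lgmn and sox3 also ended with no batch term and with batch as a random block, and that of sult2st1 with array weights. None passed without the arrays of title batch 3, and 59 did with quantile normalization.

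At Cu 0.1, gng13b and sult2st2 had the smallest p-values among named genes, at −0.88 ± 0.17 and −1.90 ± 0.35 (adjusted p = 0.0865), and neither passed. limma called 0 probe sets there, with 1136 at an unadjusted p under 0.05. The count was 12 without Cu 0.1 replicate 2, 9 without control replicate 2 and 1 without control replicate 3. It was 4 with no batch term, 1 with no filter and 1460 with array weights, where Cu 0.1 replicate 3 alone took a weight of 14.5. Over the rank of the copper concentration 235 probe sets had a trend, 132 upward and 103 downward. That split became 87 and 137 with quantile normalization, the count was 67 without control replicate 1, and it was 385 without Cu 0.25 replicate 3. It was 146, 116 and 109 without Cu 0.6 replicate 1, 2 and 3, and 155 and 142 without control replicate 2 and 3.

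**Figure D2:**
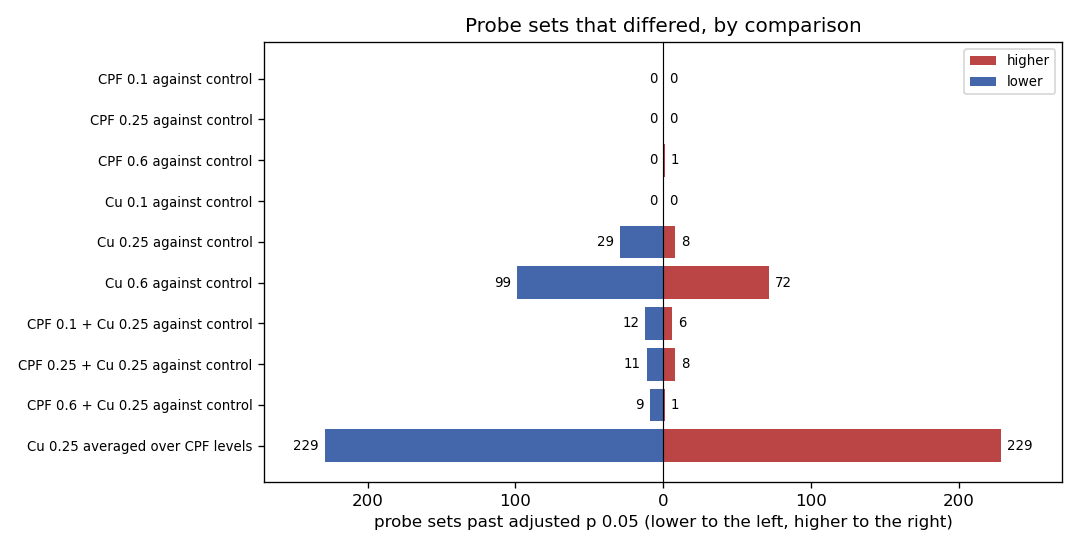
Probe sets past adjusted p 0.05 in each comparison, lower to the left and higher to the right of 0. Averaged copper had 229 in each direction and Cu 0.6 had 72 higher and 99 lower.

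**Figure D3:**
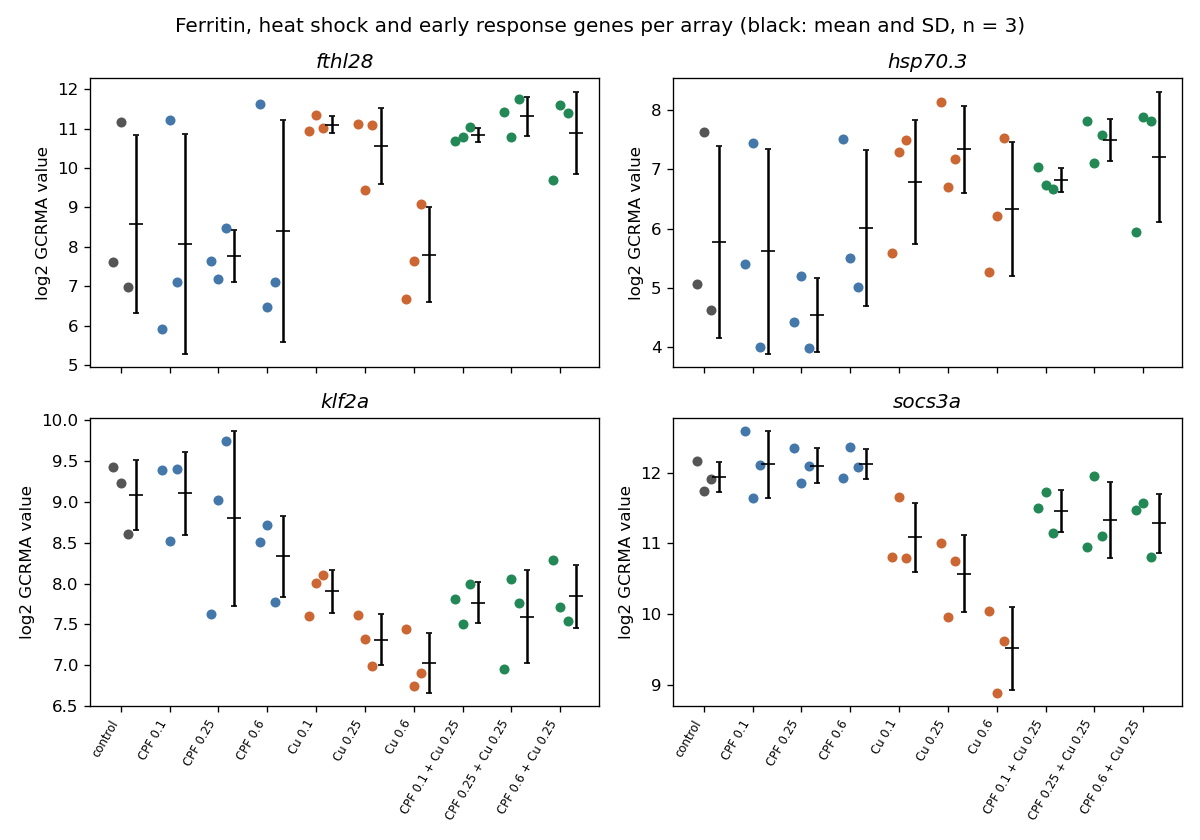
Log2 GCRMA values of fthl28, hsp70.3, klf2a and socs3a in each of the 30 arrays by group, with the mean and SD of the 3 arrays in black. The fthl28 level was 11.16 in control replicate 2 and 7.61 and 6.98 in the other control arrays.

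CPF alone was compared with control at 3 concentrations to ask what the insecticide did without copper. At CPF 0.6 tfpia, a coagulation inhibitor, rose by 1.16 ± 0.19 (adjusted p = 0.0332, 3 of 3 arrays) and was the 1 probe set past the threshold. hif1al and cdkn1bb were at 1.52 ± 0.28 and 0.74 ± 0.14 and did not pass (adjusted p = 0.065). angptl4, an inhibitor of lipoprotein lipase, was at −1.35 ± 0.27 with CPF 0.1 and −1.38 ± 0.27 with CPF 0.25 and did not pass (adjusted p = 0.289 and 0.368). ache, whose enzyme is the known target of the activated insecticide, was at 0.22, 0.49 and 0.17 at the 3 concentrations (adjusted p = 0.904, 0.907 and 0.897), and ompb at 0.05, −0.07 and 0.13.

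limma called 0 probe sets at CPF 0.1 and CPF 0.25, with 723 and 609 at an unadjusted p under 0.05, and 893 at CPF 0.6. Without control replicate 2 the counts were 5, 5 and 5. At CPF 0.25 the count was 1 without CPF 0.25 replicate 2. At CPF 0.6 it was 25, 3 and 0 without CPF 0.6 replicate 1, 2 and 3, and 4 and 0 without control replicate 1 and 3. With array weights the counts were 263, 18 and 396. The call of tfpia ended without CPF 0.6 replicate 2 or 3 or control replicate 2 or 3, with no filter, with quantile normalization, with the 2 groups fitted alone and without 4 arrays rich in liver or pancreas transcripts (adjusted p = 0.112). The CPF rank trend had 0 probe sets, with 792 at an unadjusted p under 0.05, and 21 without CPF 0.6 replicate 1, 5 without CPF 0.25 replicate 1, 4 without control replicate 2 and 1 without CPF 0.1 replicate 2 or CPF 0.6 replicate 2.

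Immediate early genes had medians of 0.33, 0.37 and 0.30 at CPF 0.1, 0.25 and 0.6, with 27, 25 and 26 of 28 positive. Their camera tests passed with the preset correlation (adjusted p = 0.478, 0.398 and 0.331 with an estimated correlation). No member passed over all probe sets, and 2, 5 and 2 did when adjusted over the list alone. Cell cycle genes had medians of −0.19, −0.20 and −0.31 (adjusted p = 0.478, 0.477 and 0.331 with an estimated correlation). Within title batches 1 and 2 the medians for CPF alone against control were 0.26 and 0.42 for immediate early genes and −0.15 and −0.22 for cell cycle genes. Ciliated cell markers had medians of −0.28, −0.23 and −0.30 in the same arrays (adjusted p = 0.757, 0.832 and 0.718 with an estimated correlation).

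CPF averaged over copper levels asked whether any CPF level differed with copper set aside. angptl4 (adjusted p = 0.0236), hif1al (0.0442) and hadhaa, a subunit of the mitochondrial trifunctional protein (0.0442), passed limma's F-test. Averaged over copper levels, angptl4 was at −1.04, −1.13 and −1.30 with CPF 0.1, 0.25 and 0.6, hadhaa at −0.67, −0.71 and −0.88, and hif1al at 0.66, 0.92 and 1.28. Of the 24 fits that left out an array angptl4 passed in 17, hadhaa in 5 and hif1al in 4. All 3 calls ended without the arrays of title batch 3 and with the compared groups fitted alone, those of hadhaa and hif1al also with no filter and with quantile normalization. The call of hadhaa ended with no batch term, a random block and median centring too, and that of hif1al without the 4 arrays rich in liver or pancreas transcripts. These were the 3 probe sets past the threshold, with 517 at an unadjusted p under 0.05. None passed without CPF 0.6 replicate 3, Cu 0.25 replicate 1 or 2, CPF 0.25 + Cu 0.25 replicate 1, CPF 0.6 + Cu 0.25 replicate 2 or control replicate 3. Only 1 passed without CPF 0.1 replicate 1 or 3, CPF 0.1 + Cu 0.25 replicate 1 or 2, CPF 0.25 + Cu 0.25 replicate 2 or 3, or control replicate 1 or 2, and 7 passed without CPF 0.25 replicate 2.

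**Figure D4:**
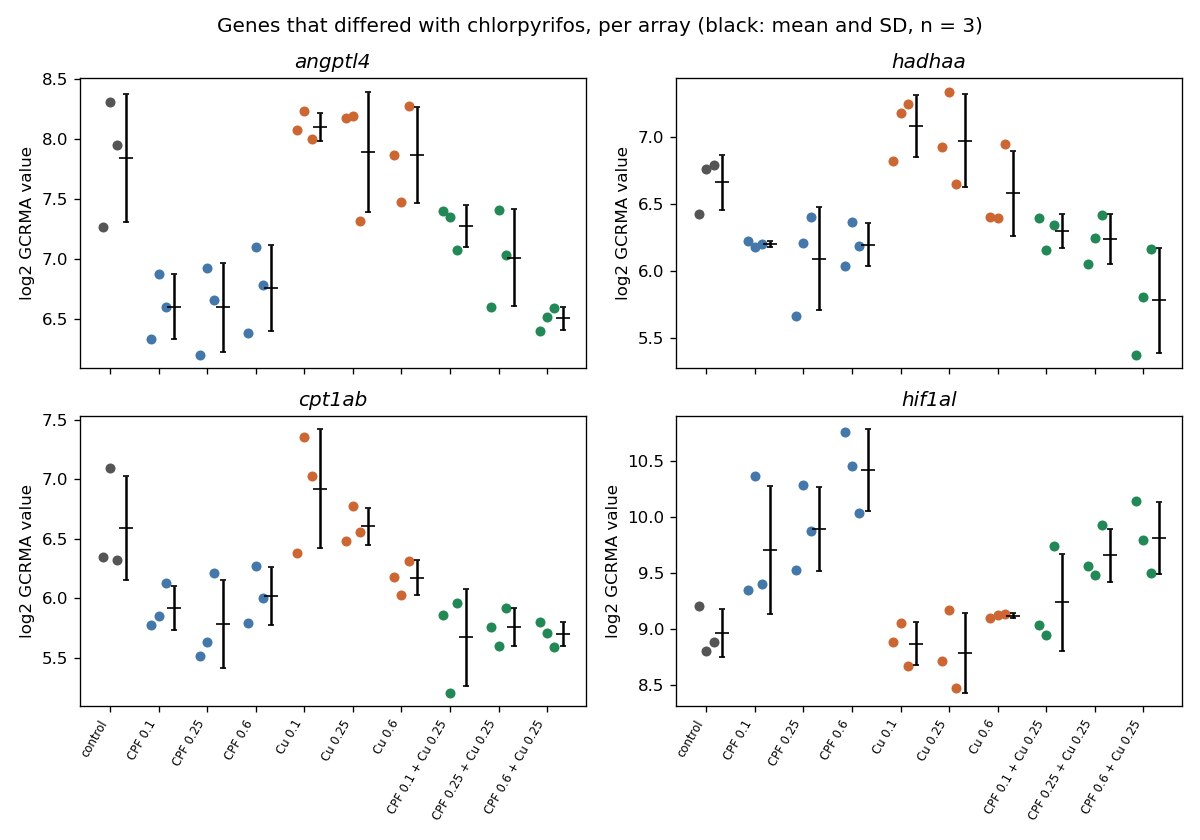
Log2 GCRMA values of angptl4, hadhaa, cpt1ab and hif1al in each of the 30 arrays by group, with the mean and SD of the 3 arrays in black. The mean of angptl4 was 7.84 in the control arrays and 6.50 at CPF 0.6 + Cu 0.25.

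The mixtures held CPF at 0.1, 0.25 or 0.6 with Cu at 0.25. Against control, gng13b fell by −0.98 ± 0.17, −1.02 ± 0.16 and −1.08 ± 0.16 and ctsba rose by 0.86 ± 0.15, 1.05 ± 0.14 and 0.78 ± 0.14, each in 3 of 3 arrays. calb2a fell by −1.61 and −1.74, and pvalb5 by −1.44 and −1.46, in the mixtures with CPF 0.25 and 0.6. angptl4 fell by −1.34 ± 0.26 with CPF 0.6 + Cu 0.25, and acaca, an enzyme of fatty acid synthesis, rose by 0.64 ± 0.11 with CPF 0.25 + Cu 0.25. The proteasome genes psma5 and psmd4b rose by 0.54 and 0.51 in that mixture, calls that ended with quantile normalization, with no batch term and with batch as a random block, and without each replicate of the mixture or control replicate 1. Every call named in this paragraph ended without the arrays of title batch 3 and with the 2 groups fitted alone, and that of angptl4 also with batch as a random block and with no filter. ctsba with CPF 0.25 + Cu 0.25 passed in all 6 fits that left out an array, angptl4 in 0 of 6 and the others in 1 to 3 of 6.

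The mixtures had 18 (6 higher), 19 (8 higher) and 10 (1 higher) probe sets past the threshold. For CPF 0.1 + Cu 0.25 the count was 2, 0 and 5 without its replicate 1, 2 and 3, 1 without control replicate 1 and 207 without control replicate 3. For CPF 0.25 + Cu 0.25 it was 6, 3 and 4 without its replicate 1, 2 and 3, and 6, 30 and 79 without control replicate 1, 2 and 3. For CPF 0.6 + Cu 0.25 it was 0, 2 and 0 without its replicate 1, 2 and 3, and 0, 26 and 0 without control replicate 1, 2 and 3. Without the arrays of title batch 3 the counts were 1, 0 and 0. Quantile normalization changed the higher and lower counts to 4 and 4 for CPF 0.1 + Cu 0.25 and to 11 and 34 for CPF 0.25 + Cu 0.25, and median centring to 6 and 5 and to 30 and 30.

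Against Cu 0.25 alone, the mixtures had 0, 0 and 1 probe sets past limma's threshold, with 552, 596 and 610 at an unadjusted p under 0.05. The 1 call was lost without Cu 0.25 replicate 1 or 2 or CPF 0.6 + Cu 0.25 replicate 1 or 2, and 6 passed without Cu 0.25 replicate 3. The GAPDH 3′ minus 5′ difference was at most 0.818 in the mixtures and at least 0.845 at Cu 0.25. For CPF 0.25 + Cu 0.25, 1 passed without Cu 0.25 replicate 1. Against CPF alone they had 0, 42 (17 higher, 25 lower) and 0, with 715, 1037 and 654 at an unadjusted p under 0.05. The 17 and 25 became 12 and 30 with quantile normalization. The 42 became 3, 11 and 4 without CPF 0.25 replicate 1, 2 and 3 and 16, 0 and 3 without CPF 0.25 + Cu 0.25 replicate 1, 2 and 3. At CPF 0.1, 10 passed without CPF 0.1 + Cu 0.25 replicate 3, and at CPF 0.6, 17 and 43 passed without CPF 0.6 replicate 1 and 3.

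No probe set passed limma's test of the CPF by Cu interaction, with 386 at an unadjusted p under 0.05 and a smallest adjusted p of 0.99994. Without CPF 0.6 replicate 1 the count was 4, and without control replicate 2 it was 1. The interaction test recovered 7.58% of simulated changes of 0.5, so small departures from additivity were not detectable with these arrays. Any difference among the 10 groups was called for 139 probe sets, 74 without Cu 0.6 replicate 3 and 85 without control replicate 1.

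Across 10531 probe sets, which are not independent replicates, the fold changes of the mixtures against control correlated with those of Cu 0.25 at a mean r of 0.710 and with those of CPF at 0.573. Unchanged groups sharing the control arrays gave a mean of 0.477 and 0.489 in simulation and at most 0.731 and 0.775, so neither r exceeded the range of unchanged groups. The covariances were 0.0589 and 0.0419, against 0.0237 and 0.0260 simulated and at most 0.0643 and 0.0593. From separate arrays, the copper response with CPF and the copper response without it correlated at a mean r of 0.374. The highest simulated mean was 0.319. The values were 0.484, 0.419 and 0.218 with CPF 0.1, 0.25 and 0.6, each against the same Cu 0.25 and control arrays. The mean was 0.276 without Cu 0.25 replicate 1 and 0.225 without the arrays of title batch 3. The simulations were of the full design only. The covariance was 0.0269, against at most 0.0145 simulated. The CPF response with copper and without it correlated at a mean r of 0.185, below the highest simulated mean of 0.342. The values were 0.314, 0.139 and 0.103 with CPF 0.1, 0.25 and 0.6. The covariance of these CPF responses was 0.00995, against at most 0.0252 simulated. The r of 0.710 became 0.579 without Cu 0.25 replicate 1, and the r of 0.573 became 0.701 without control replicate 3.

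Copper and CPF at the same number were compared directly, in a comparison added after seeing the data; the numbers need not stand for equal doses. limma called 0, 51 (10 higher with copper, 41 lower) and 132 (40 higher, 92 lower) probe sets at 0.1, 0.25 and 0.6, with 618 at an unadjusted p under 0.05 at 0.1. At 0.1 the count was 2 without CPF 0.1 replicate 2. At 0.25 it was 13, 18 and 7 without CPF 0.25 replicate 1, 2 and 3, 0 without Cu 0.25 replicate 2 and 79 without Cu 0.25 replicate 3. At 0.6 it was 22 and 254 without CPF 0.6 replicate 2 and 3, and 84 and 59 without Cu 0.6 replicate 2 and 3.

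Markers of other tissues varied between arrays. The mean over liver transcripts, a list chosen after seeing the data, was highest in CPF 0.25 replicate 1 (5.06) and control replicate 1 (4.78). That over pancreas transcripts was highest in CPF 0.25 replicate 1 (5.02) and CPF 0.25 replicate 3 (4.27). The added fit left out CPF 0.25 replicate 1 and 3, Cu 0.25 replicate 3 and CPF 0.6 replicate 2, and kept control replicate 1. For averaged copper, 2 of 9 liver genes fell (adjusted p = 0.0511 with an estimated correlation) and 0 of 9 pancreas genes passed (adjusted p = 0.284 with an estimated correlation). Without 4 of the arrays rich in these transcripts, CPF 0.6 had 11 probe sets past the threshold and any difference among groups 59.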

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

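All tests of explanations weighed in this part were chosen after the results were seen, and so were the counts over other splits of the arrays, except those for copper against CPF at the same number.

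Most olfactory genes fell with averaged copper. Of the 17 in the fixed olfactory lists 12 were negative and 5 positive, and 9 passed. The median over all 17 was −0.42, with an SD of 0.541. These 9 calls came from the fit with batch terms in which the pattern was seen, so they are no separate test of a title batch. The batch terms changed the calls of 79 other genes. With them ompb, named in advance, was at −1.26 ± 0.19 and without them at −1.21. Within title batches 1 and 2 it was at −1.21 and −1.32, which argues against a title batch as the whole source for ompb. For the 17 genes as a set a title batch stays open. Their medians within title batches 1 and 2 were −0.26 and −0.48, smaller than the spread between genes. Less olfactory epithelium in the copper arrays stays open. The 29 epithelium and skin markers had a median of −0.10 with an SD of 0.367 between genes. That SD is not an error of the median, so it cannot say whether −0.10 differs from −0.42. The 20 ciliated cell markers had a median of 0.14, but −0.17 and 0.30 within title batches 1 and 2. They do not decide whether the copper arrays held less olfactory epithelium. Fewer neurons and less transcript per neuron were not tested.

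High fthl28 and hsp70.3 went with averaged copper, but also appeared in control replicate 2. A title batch is argued against as the whole source of these levels. Within title batches 1 and 2, fthl28 spanned 5.72 and 5.27 log2 units and hsp70.3 spanned 3.81 and 3.90. Those ranges hold arrays of all treatments, so they cannot decide whether a title batch shaped the copper difference. Within title batches 1 and 2 that difference was 2.48 and 2.71 for fthl28 and 1.29 and 1.78 for hsp70.3, from 1 or 2 arrays a group. A level that follows the copper concentration stays open: relative to Cu 0.25, fthl28 at Cu 0.6 was −2.69 ± 1.25 (SE) and hsp70.3 −0.92 ± 0.87 (limma adjusted p = 0.616 and 0.846). Handling of the fish may differ between samples, and no test of it was possible with these labels.

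For all CPF levels against none, 19 fatty acid oxidation genes had a median of −0.27, with 0 past the threshold over all probe sets and 11 lower when adjusted over the list alone (adjusted p = 0.0306 with an estimated correlation). The list was chosen on these arrays, without the genes that led to it, so tests on it decide nothing, and the 3 control arrays alone, a title batch and feeding state stay open. The mixtures against Cu 0.25, part of the same comparison, gave a median of −0.28. Within title batches 1 and 2 the medians were −0.16 (SD 0.162) and −0.41 (SD 0.179), and for the mixtures against Cu 0.25 they were −0.0235 and −0.46. The GAPDH 3′ minus 5′ difference was 0.698 to 0.818 in the 9 mixture arrays and 0.845 to 0.948 in the 3 Cu 0.25 arrays, and RNA quality stays open too.

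Interaction p-values adjusted over the 110 named genes were 0.0156 for actl6a, bzw1b, cdkn1bb, kdm5c, psmd4b, taldo1 and tfpia, 0.0186 for cdh1, mob3a and s100a10b, 0.0342 for runx2a, 0.0437 for ctsd, 0.0452 for ppp1cab and 0.0454 for tmx1. Of these 14 genes, 10 had been named for their small interaction p on the same arrays and the other 4 for their difference from the same controls, so these values are not evidence of an interaction. Over all probe sets the smallest adjusted p was 0.99994.

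The control probe sets for GAPDH, which the comparisons do not use, showed a 3′ minus 5′ difference above the highest control array (0.821) in all 3 arrays of CPF 0.1, Cu 0.1 and Cu 0.25, with lowest values of 0.854, 0.829 and 0.845. Chance gives this in 5% of groups, and 27 combinations of 9 groups and 3 measures were looked at. The spike probe sets and the acta1 3′ minus 5′ difference gave no group above the highest control array. Groups below the lowest control array were not part of these combinations. The mean over the spike probe sets was below it in all 3 arrays of CPF 0.1 + Cu 0.25 (highest 8.959, lowest control array 9.002). The cause was not tested.

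Of 100 groupings of the arrays, the real one included, 1 gave as many probe sets as the real grouping for averaged copper (458, highest other 0). The same held for CPF averaged over copper levels (3, highest other 1), any difference among groups (139, highest other 3) and the copper rank trend (235, highest other 181, next 12). A share of 1 of 100 is the smallest these groupings can give, and it is not adjusted for the number of comparisons. The groupings did not keep arrays within their title batch. For CPF averaged over copper levels chance stays open, since its count of 3 fell as low as 0 when 1 array was left out. All CPF levels against none also gave 1 of 100 (28, highest other 2), but that comparison was chosen on these arrays, so its share is not independent evidence. Chance also stays open for the number of lists past camera's threshold with averaged copper, since 14 of 100 groupings gave 11 or more (highest other 15). All 100 groupings reached the real count of 0 for the interaction (highest other 97, next 4) and for the CPF rank trend (highest other 559, next 11). Each large count came from a single grouping. The groupings for the interaction mixed all 24 arrays without holding the copper or CPF level. A copper or CPF difference could therefore enter those counts, and they are no test of an interaction. A structure among the arrays apart from the groups and correlated probe sets in a grouping are other possible sources, and none was tested. For the median of the immediate early genes with all CPF levels, 1 of 100 groupings was as large (0.35, highest other 0.32), in the same comparison chosen on these arrays.

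With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the highest count, 1 of 10 splits, for Cu 0.25 (37, highest other 2), Cu 0.6 (171, highest other 1), the mixtures against control (18, 19 and 10, highest others 0, 1 and 0), CPF 0.6 + Cu 0.25 against Cu 0.25 (1, highest other 0), CPF 0.25 + Cu 0.25 against CPF 0.25 (42, highest other 1) and copper against CPF at 0.25 (51, highest other 9) and 0.6 (132, highest other 2). For CPF 0.6 against control 3 of 10 splits gave its count of 1 (highest other 1). For the comparisons with a real count of 0, 10 of 10 splits reached it: CPF 0.1, CPF 0.25 and Cu 0.1 against control (highest others 63, 1 and 0), the mixtures with CPF 0.1 and 0.25 against Cu 0.25 (2 and 0), the mixtures with CPF 0.1 and 0.6 against CPF (1 and 0) and copper against CPF at 0.1 (0). The split with 63 set CPF 0.1 replicate 1 and 3 and control replicate 3 against the others, which does not follow the title batches. On the first principal component those arrays lay at 8.4, 7.7 and −4.9, and CPF 0.1 replicate 2 and control replicate 1 and 2 at −17.0, −27.7 and −16.3. Between 9831 and 9919 probe sets exceeded 4 in the former, against 10129 to 10416 in the latter. Whether this difference or correlated probe sets gave the count of 63 was not tested.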

How the results depend on the processing

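The fit without 4 arrays, copper against CPF at the same number and all CPF levels against none were chosen after seeing the data. For named genes under alternatives other than leaving out an array, 2743 values kept their side of the threshold. Another 351 no longer passed and 44 newly passed. Leaving out an array, these were 3040, 461 and 15. The values that kept their side include those of named genes that passed in neither fit, so these counts do not give the share of calls that held. No value that passed in either of the fits compared changed direction. Changes of direction between values that did not pass were not counted, and F-tests have no direction. No paired analysis was possible because replicate numbers were given in accession order only. Where 1 array of a group was left out, the other 2 were assumed to vary like the other groups. Except where fewer arrays were fitted, the cause was not tested.

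The estimation of array weights stopped before it converged, and Cu 0.1 replicate 3 took a weight of 14.5. With array weights, the counts against control were 263, 18 and 396 for CPF 0.1, 0.25 and 0.6, 1460 for Cu 0.1, 374 for Cu 0.6 and 1045, 729 and 166 for the mixtures with CPF 0.1, 0.25 and 0.6. Against Cu 0.25 they were 1 and 2 for the mixtures with CPF 0.1 and 0.6, and against CPF alone 17, 73 and 128. They were 782 for averaged copper, 34 for averaged CPF, 2099 for any group, 495 for the copper trend and 223 for the CPF trend. With no batch term they were 5 for CPF 0.6, 4 for Cu 0.1, 31 for CPF 0.25 + Cu 0.25, 1 and 0 for the mixtures with CPF 0.1 and 0.6 against Cu 0.25, 17 for CPF 0.6 + Cu 0.25 against CPF 0.6, 4 for the CPF trend, 4 for Cu 0.1 against CPF 0.1 and 68 for all CPF levels. With batch as a random block they were 5 for CPF 0.6, 1 and 0 for the mixtures with CPF 0.1 and 0.6 against Cu 0.25, 26 and 18 for those with CPF 0.25 and 0.6 against CPF, and 4 for the CPF trend.

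Without the arrays of title batch 3 the counts were 3 for CPF 0.6, 0 for Cu 0.25, 36 for Cu 0.6, 1, 0 and 0 for the mixtures, 8 for CPF 0.25 + Cu 0.25 against CPF 0.25, 229 for averaged copper, 0 for averaged CPF, 61 for any group, 51 and 2 for the copper and CPF trends and 71 for Cu 0.6 against CPF 0.6. The correlation of mixtures with Cu 0.25 was 0.546 and that of the copper responses from separate arrays 0.225. With only the groups compared, they were 0 for CPF 0.6, 50 for Cu 0.6, 0 for each mixture, 0 for CPF 0.6 + Cu 0.25 against Cu 0.25, 0 for CPF 0.25 + Cu 0.25 against CPF 0.25, 0 for averaged CPF and 67 for the copper trend. Without 4 arrays rich in liver or pancreas transcripts they were 11 for CPF 0.6, 4 and 6 for the mixtures with CPF 0.25 and 0.6 against Cu 0.25, 5 for CPF 0.25 + Cu 0.25 against CPF 0.25, 6 for averaged CPF, 59 for any group and 1 for the CPF trend. Averaged copper had 0 within title batch 1 and 38 within title batch 2.

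With no filter the counts were 0 for CPF 0.6, 1 for Cu 0.1 and 1 for averaged CPF. With the stricter filter they were 41 and 18 for the mixtures with CPF 0.25 and 0.6, 1 for CPF 0.1 + Cu 0.25 against Cu 0.25, 1 for CPF 0.6 + Cu 0.25 against CPF 0.6 and 1 for the CPF trend. With quantile normalization they were 0 for CPF 0.6, 59 for Cu 0.25, 8, 45 and 28 for the mixtures, 1 for CPF 0.1 + Cu 0.25 against Cu 0.25 and 1 for averaged CPF. With median centring they were 11 and 60 for the mixtures with CPF 0.1 and 0.25, 1 for CPF 0.6 + Cu 0.25 against CPF 0.6, 3 for the CPF trend and 3 for Cu 0.1 against CPF 0.1. With a trended and robust prior CPF 0.1 + Cu 0.25 had 9. With an estimated correlation 1 list passed for averaged copper.

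Leaving out an array gave 0 to 5 for CPF 0.1, 0 to 5 for CPF 0.25, 0 to 25 for CPF 0.6, 0 to 12 for Cu 0.1, 0 to 39 for Cu 0.25 and 59 to 135 for Cu 0.6. The mixtures with CPF 0.1, 0.25 and 0.6 had 0 to 207, 3 to 79 and 0 to 26, against Cu 0.25 those with CPF 0.25 and 0.6 had 0 to 1 and 0 to 6, and against CPF they had 0 to 10, 0 to 16 and 0 to 43. Averaged copper had 299 to 681, averaged CPF 0 to 7, the interaction 0 to 4, any group 74 to 197, the copper trend 67 to 385 and the CPF trend 0 to 21. Copper against CPF had 0 to 2, 0 to 79 and 22 to 254, and all CPF levels 2 to 58. The correlation of mixtures with Cu 0.25 ran from 0.579 to 0.788 and with CPF from 0.516 to 0.701.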

Other observations

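In this part the comparison of all CPF levels with none, and each list except the immediate early genes, were chosen after the result was seen, and no explanation is offered. For averaged copper, 28 of 42 proteasome genes rose, with a median of 0.26 and 41 of 42 positive (adjusted p = 0.0104 with an estimated correlation). The medians were 0.24 and 0.31 within title batches 1 and 2. Of 24 genes of lysosomal proteases and their partners 7 rose (adjusted p = 0.124 with an estimated correlation), as did 2 of 9 complement genes (adjusted p = 0.124 with an estimated correlation). The 13 pineal and photoreceptor genes had a median of 0.27 with 0 past the threshold (adjusted p = 0.926 with an estimated correlation).

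All CPF levels against none, averaged over copper levels (18 arrays against 6), gave 28 probe sets, 21 higher and 7 lower, or 20 and 14 with quantile normalization. Lower were angptl4 by −1.16, cpt1ab (a carnitine palmitoyltransferase) by −0.82, hadhaa by −0.75 and eci1 (an enoyl-CoA isomerase) by −0.55. Higher were hif1al by 0.95, ccn2a by 0.81, the activity-regulated npas4a by 0.67, junba by 0.64 and acaca by 0.34. npas4a and junba were named after their values were seen. Of 19 other fatty acid oxidation genes 0 passed over all probe sets and 11 fell when adjusted over the list alone, with a median of −0.27 and 0 positive (adjusted p = 0.0306 with an estimated correlation). Of 100 groupings of the arrays 1 gave as large a median, with 0.21 the highest other, which is not independent evidence since the list was chosen on these arrays. Of 28 immediate early genes 27 were positive and 2 passed (adjusted p = 0.105 with an estimated correlation). The count was 2 without Cu 0.25 replicate 2, 58 without Cu 0.25 replicate 1, 47 without CPF 0.25 replicate 2 and 16, 16 and 17 without control replicate 1, 2 and 3.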
